A study of Mus musculus with 13 samples.

How the data were processed

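The series holds 13 RNA-seq libraries of mouse small intestine in 5 groups. 9 libraries came from crypts, the epithelial pockets that house the intestinal stem cells and Paneth cells, taken from mice given beta-naphthoflavone for 6 weeks. This compound activates the aryl hydrocarbon receptor and so switches on the AhCre recombinase, named in the labels of the organoids and of the run 440 crypts, which deletes floxed alleles in the epithelium. The crypt groups were wild type (WT, n = 3), Eed knockout (KO, n = 3) and Ezh2 KO (n = 3). 4 libraries came from crypt-derived organoids, epithelial cultures induced with the same compound for 10 days, as WT (n = 2) and Eed KO (n = 2). Libraries are named below by group, sequencing run (385 or 440, per the labels) and title number, as in Eed KO 385_1.

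Per the labels' protocols, crypts were obtained after removal of villi and EDTA chelation, RNA was extracted with TRIzol, and libraries were made with a strand-specific kit for polyadenylated RNA. The authors deposited raw read counts per gene, as 1 table for each run, with Ensembl gene identifiers, biotypes and positions per the file headers. Per the submitters' processing notes, the build was GRCm38 and the tools were TopHat2 2.0.12, Bowtie 0.12.9, HTSeq and DESeq2, with no role stated for any of them. Whether counting used the strand of the reads is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. Reads from near-identical copies, such as the alpha-defensins and processed pseudogenes, can be split or dropped by counting, so the values of those genes are uncertain.

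Run 385 held WT crypts 385_1 and 385_2, Eed KO crypts 385_1 and 385_2 and all 4 organoid libraries. Run 440 held WT crypt 440_1, Eed KO crypt 440_1 and the 3 Ezh2 KO crypts. The table of run 385 listed 23969 genes and that of run 440 listed 22634, and 21420 identifiers were in both. Of the shared identifiers, 397 had another symbol and 1284 another start or end in the 2 tables, so the authors' annotation differed between runs. Crypt comparisons used the shared identifiers only, which left out at most 0.196% of the counts of any library of run 385 and 0.0662% of any library of run 440. Symbols came from the GENCODE M21 annotation, which named 24702 of the 25183 identifiers in either table, and otherwise from the deposited tables. Coordinates are those of the deposited tables, in GRCm38.

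Depth ran from 11421666 to 18300644 counts per library. A count of 0 was given a floor of 3 counts, here summed over the libraries of a group, and folds against such a group are printed as lower bounds. With 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Levels are CPM, the unit of counts scaled to library size, computed from the deposited counts with TMM-adjusted library sizes, as mean ± SD over the libraries of a group. Levels across the 2 runs are set side by side without correction, and fold changes come from the fits with the run as a term, so a fold can differ from the ratio of 2 means.

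Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, TMM normalization, the low-count filter of edgeR by group (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment with a threshold of 0.05. All adjusted p-values below are from this test unless another is named. The 9 crypt libraries were fitted together with group and run as terms (14406 genes, 5 residual degrees of freedom). The 4 organoid libraries were fitted on their own (12958 genes, 2 residual degrees of freedom). The difference between the Eed effect in crypts and in organoids was tested as an interaction over all 13 libraries (14761 genes, 7 residual degrees of freedom). Standard errors (SE) of log2 fold changes were derived from the F statistic. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

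25 gene lists for cell types, pathways and complexes were fixed before the data were examined, as were the comparisons, the main tests and the rule for naming genes. For each list, the members past the threshold are counted over all genes tested and also with adjustment over the list alone. Whole lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. No list was past the threshold in any comparison when camera estimated that correlation from the data (1 was among genes tested in both crypts and organoids), and the adjusted p with an estimated correlation is printed beside each list. The directional fry test, which asks whether the genes of a list move on balance one way, was run as an alternative. Lists with fewer than 3 measured genes were not tested, which were the sex-linked list in crypts (2 of 6 genes measured) and the immune list in organoids (2 of 28 genes measured).

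Genes were named by this rule for each comparison: Eed, Ezh2 and Ezh1; the 8 genes with the largest rise and the 8 with the largest fall among called genes with no overlap between groups and a mean of at least 1 log2 CPM in the higher group, leaving out provisional symbols and antigen receptor segments; up to 4 members of each list with the smallest p; and a fixed set of markers of stem, secretory and absorptive cells and cell cycle inhibitors. For Eed against Ezh2 KO crypts and for crypts against organoids, the genes named on either side and the 5 with the smallest p in each direction were taken.

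Alternatives were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, 1 fit of all 13 libraries, no run term, each run alone, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the comparison of 1 Eed KO with 1 WT crypt within run 440, the gene lists within run 440, Eed KO crypts without the Ezh2 KO libraries, the lists of the interaction over genes tested in both systems, tests without genes of the X and Y chromosomes, and the interaction without each library. The deviations of same-numbered Eed KO and WT crypts from their group means correlated at 0.448, 0.508 and 0.581 over the 5000 genes with the highest mean. The numbers were used as pairs only in the block alternative, and the main fits hold the run alone. These correlations follow the run, since Eed KO 385_1 correlated at 0.660 with WT 385_2, and the labels name no pairs. After the run term was removed, the correlations of pairs within run 385 were -0.23 and -0.50. Removing that term draws such values below 0 by construction (-1 for the pair of run 440), so they decide no pairing. No pair of libraries in any group agreed within sampling noise (lowest chi-square per degree of freedom 13.1), so none was taken as a duplicate.

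The analysis was tested on simulated counts with the means, library sizes and dispersions of the real libraries and 100 genes changed 2-fold and 100 changed 4-fold, drawn from genes with a mean above 20 counts. The test recovered 17% of 2-fold and 81% of 4-fold changes for Eed KO against WT crypts, 24% and 72% for Ezh2 KO against WT crypts, 18% and 80% for Eed against Ezh2 KO crypts, 77% and 100% for the organoids, and 2% and 54% for the interaction. False calls numbered 6, 5, 3, 26 and 1 in the same order.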

Results

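The 13 libraries cover crypts of WT (n = 3), Eed KO (n = 3) and Ezh2 KO mice (n = 3) and organoids of WT (n = 2) and Eed KO (n = 2) origin. Each held between 11421666 and 18300644 counts. Mitochondrially encoded transcripts are a rough sign of RNA and cell quality. They took 3.71% to 17.99% of counts in Eed KO crypts, with the lowest share in 440_1, and 8.65% to 14.5% in WT crypts. In Ezh2 KO crypts their share was 3.85% to 6.46%, and in organoids 7.98% to 9.83%. The labels give no sex, but levels of Xist, the RNA that silences an X chromosome in females, and of the Y-linked Ddx3y differed within groups. In run 385, the WT crypts had 2.48 and 2.58 Xist and 33.0 and 54.0 Ddx3y CPM (on total counts), a male pattern. The Eed KO crypts of that run had 1915 and 3592 Xist with at most 1 Ddx3y count, a female pattern. All 5 crypts of run 440 had a female pattern, with 324.8 to 1446 Xist and no Ddx3y count. Eed KO organoids had a male pattern (48.9 and 54.0 Ddx3y) and WT organoids a female one (1265 and 1384 Xist). Organoid strain labels also differed, FVB for WT and C57BL/6-FVB for Eed KO.

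Eed (ENSMUSG00000030619, chromosome 7, 89954656 to 89980983, GRCm38) encodes the Polycomb repressive complex 2 (PRC2) subunit that binds trimethylated lysine 27 of histone H3 and that the complex needs for its activity. Its transcript stood at 19.003 ± 5.17 CPM in Eed KO crypts (n = 3) against 54.1 ± 5.27 in WT (n = 3). The log2 fold change was -1.51 ± 0.21 (SE), with adjusted p = 0.00133. In Eed KO organoids (n = 2) it stood at 25.3 ± 8.47 against 69.1 ± 7.44 in WT (n = 2), a log2 fold change of -1.45 ± 0.23 (adjusted p = 0.00699). Ezh2 (ENSMUSG00000029687, chromosome 6, 47530274 to 47595341) and Ezh1 (ENSMUSG00000006920, chromosome 11, 101191115 to 101226463) encode the alternative methyltransferases of the complex. Ezh2 transcript was 18.9 ± 2.26 CPM in Ezh2 KO crypts against 85.4 ± 12.2 in WT, or 71.5 in the WT library of the same run. The log2 fold change was -1.82 ± 0.17 (adjusted p = 0.0148). This call was lost within run 440 alone (-1.92) and without Ezh2 KO 440_2, Ezh2 KO 440_3 or WT 385_2, with adjusted p from 2.95e-17 to 0.183 over all alternatives. The remaining transcript can hold RNA from undeleted cells or from an allele that is transcribed without the deleted exons. The labels do not say which exons were removed.

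What does loss of Eed change in crypts? Transcription factors of other body regions and of the embryo, silent in WT crypts, were present in all 3 Eed KO crypts, together with the cell cycle inhibitor Cdkn2a. Transcripts of dividing cells, of the crypt base stem cell and of Paneth cells were lower. At the gene level, 1932 genes were higher and 1531 lower of 14406 tested. Within run 385 alone, 2326 genes were higher and 1664 lower of 14053. In run 440, where both have a female pattern, 1 Eed KO against 1 WT crypt gave 741 higher and 476 lower. With same-numbered libraries as a block and no Ezh2 KO library in the fit, 1046 were higher and 543 lower, of which 1042 and 540 were among those above. Leaving out the Ezh2 KO libraries with no block gave 1465 and 999.

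Hox genes set position along the body axis, and 33 of 35 measured were higher in Eed KO crypts (33 adjusted over the list alone). Their median log2 fold change was 4.93, or 4.61 with genes near 0 counts at their bound. For Hox genes camera gave adjusted p = 1.83e-25, and adjusted p = 0.0567 with an estimated correlation. Hoxb13 (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447) marks the hind end of the embryo. It reached 60.3 ± 16.0 CPM against no count in 3 WT crypts, at least 807-fold higher (adjusted p = 0.000209). Hoxd13 reached 30.9 ± 3.30 CPM, at least 395-fold higher. Hoxa9 stood at 40.4 ± 9.19 CPM against 1 WT count in all, a ratio of 1521 (95% counting interval 273 to 60112). Hoxa10 stood at 52.4 ± 12.7 CPM against 3 counts, a ratio of 656 (224 to 3182).

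Among transcription factors of tissues other than intestine, 58 of 71 measured rose and 2 fell, among them Lmx1a (59 and 2 adjusted over the list alone). The list holds 105 genes, of which 102 were in the tables of both runs, and the others of these had too few counts to be tested. A gene silent in WT is tested mainly where a knockout raises it, so the share of measured genes overstates the share of the list. Their median was 7.04, or 6.05 at bounds, and camera gave adjusted p = 2.87e-39, and adjusted p = 0.0567 with an estimated correlation. En2, a midbrain and hindbrain factor, reached 35.5 ± 5.48 CPM (at least 455-fold higher) and the endoderm and endothelial factor Sox17 33.7 ± 8.75 (at least 424-fold). The forebrain factor Sim2 reached 31.3 ± 6.41 (at least 409-fold), and Zic1 of the neural tube 47.1 ± 11.9 against 1 WT count (ratio 1765, 316 to 69740.0). Lhx2, a forebrain and hair follicle factor, stood at 18.3 ± 2.81 against 0.140 CPM (log2 fold change 6.88 ± 0.56). Other large rises, all without a WT count, were Ano3, an anoctamin of neurons (54.7 ± 40.3 CPM, at least 641-fold), and Tmprss6, a liver protease that lowers hepcidin (33.7 ± 9.26, at least 451-fold). The limb factor Sp8 reached 31.1 ± 9.72 CPM (at least 394-fold).

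**Figure D1:**
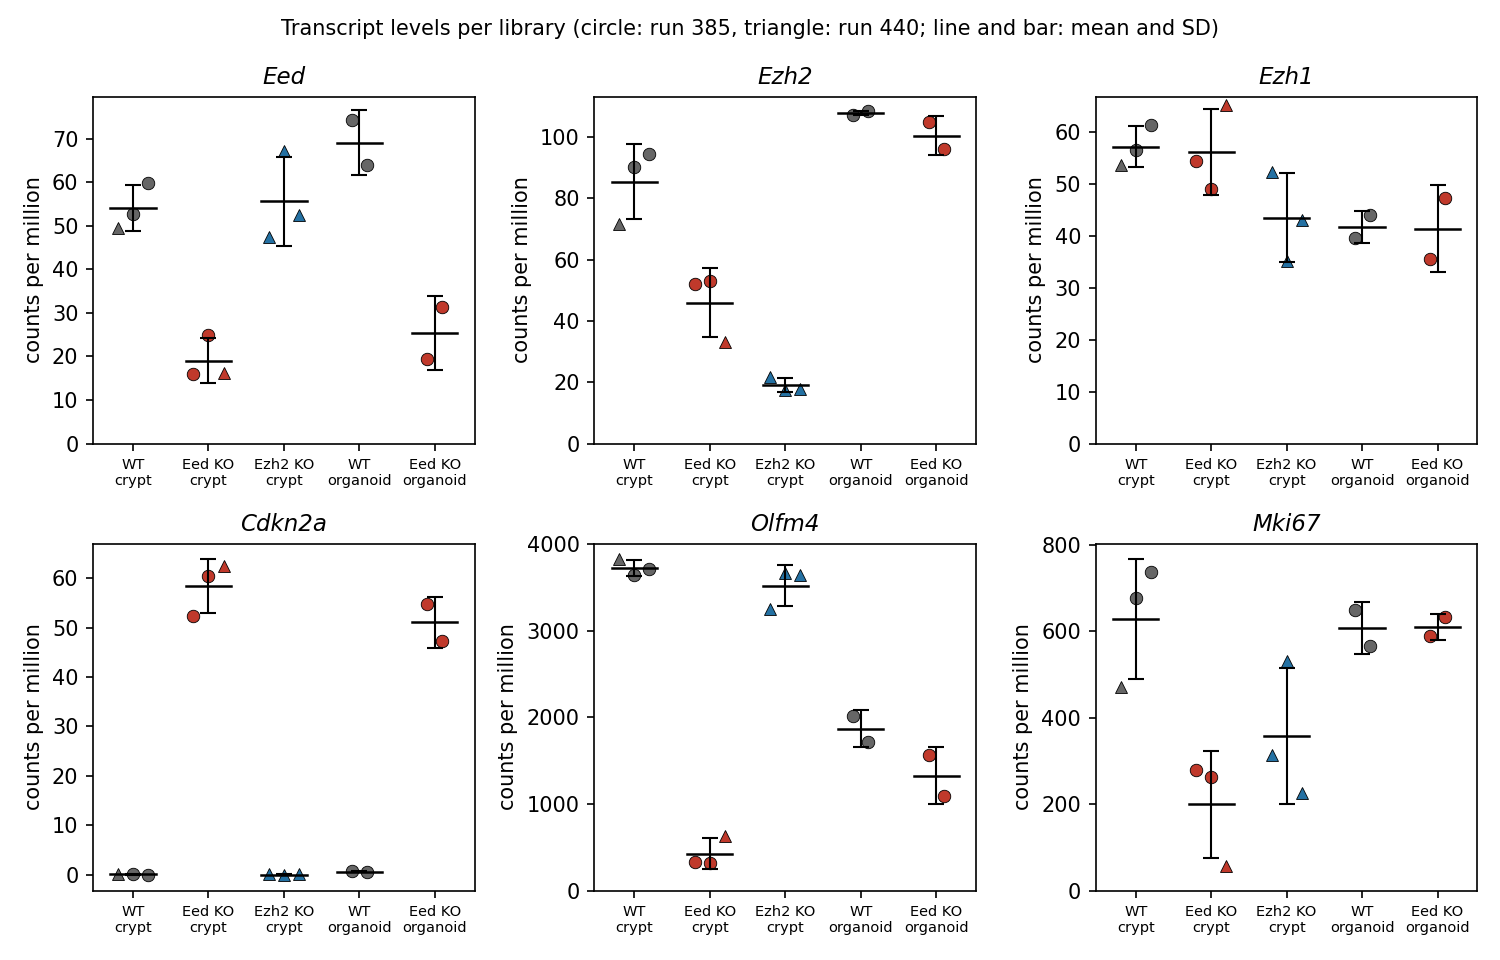
CPM (linear y axis) of Eed, Ezh2, Ezh1, Cdkn2a, Olfm4 and Mki67 in each of the 13 libraries by group, with circles for run 385, triangles for run 440, and line and bar for mean and SD. Cdkn2a lies at 58.4 ± 5.41 in Eed KO crypts and 51.0 ± 5.17 in Eed KO organoids, and under 1 in the WT and Ezh2 KO groups.

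Cell cycle inhibitors went both ways: of 7 measured, 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.444). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) encodes p16 and p19, which restrain CDK4 and MDM2. It stood at 58.4 ± 5.41 CPM against 0.0497 ± 0.0452, which is 2 WT counts in all (ratio 1139.6, 315 to 9415; adjusted p = 1.26e-05). The p53 target Cdkn1a, which encodes p21, rose from 38.6 ± 4.75 to 287 ± 88.5 CPM (log2 fold change 2.87 ± 0.23, adjusted p = 0.00016). Cdkn1b (-1.21 ± 0.17) and Cdkn2c (-0.97 ± 0.16) fell. Of 20 measured p53 targets, 14 rose and none fell by edgeR (14 adjusted over the list alone), among them Gdf15 (4.75 ± 0.28), Plk2 (4.53 ± 0.34) and Psrc1 (3.22 ± 0.20). For p53 targets camera gave adjusted p = 1.51e-09, and adjusted p = 0.0567 with an estimated correlation. Proliferation genes moved the other way, with 34 of 42 lower and 1, the G1 cyclin Ccnd2, higher (38 and 1 adjusted over the list alone). Their median was -1.17, and camera gave adjusted p = 7.26e-15, and adjusted p = 0.0913 with an estimated correlation. Mki67 (ENSMUSG00000031004, chromosome 7, 135689788 to 135716379), a coat protein of mitotic chromosomes, fell from 628 ± 139 to 199 ± 124 CPM (-1.93 ± 0.41, adjusted p = 0.00957). Cyclin A2 (Ccna2) fell from 191 ± 0.555 to 63.8 ± 1.67 (-1.58 ± 0.13) and survivin (Birc5) from 95.4 ± 20.4 to 32.3 ± 8.28 (-1.57 ± 0.13).

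Crypt base stem cell genes were lower as a list, with 11 of 28 lower and 3 higher (13 and 5 adjusted over the list alone). For stem cell genes camera gave adjusted p = 0.0245, and adjusted p = 0.550 with an estimated correlation. The list call was lost for 1 Eed KO against 1 WT crypt of run 440. Olfm4 (ENSMUSG00000022026, chromosome 14, 80000302 to 80021930), a secreted marker of these cells, fell from 3727 ± 93.5 to 424 ± 179 CPM (-3.21 ± 0.23, adjusted p = 0.000115). Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), the R-spondin receptor that defines them, fell from 103.2 ± 12.0 to 43.9 ± 12.1 (-1.24 ± 0.17, adjusted p = 0.00146). The urea transporter Slc14a1 fell by 4.85 ± 0.47 on the log2 scale, and the 3 that rose were Prom1 (1.16 ± 0.19), Cd44 and Gkn3. Ascl2, a Wnt-driven stem cell factor, stood at 12.5 ± 2.15 against 22.1 ± 3.60 CPM (adjusted p = 0.0963). Wnt targets were split, with 5 higher and 4 lower of 20 (6 and 4 adjusted over the list alone; camera adjusted p = 0.668). Lef1 (3.17 ± 0.45) and Notum (3.79 ± 0.62) rose, and Axin2 and Lgr5 fell. In the Notch pathway, 3 of 15 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.294).

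Paneth cells make antimicrobial proteins at the crypt base, and 10 of 25 measured Paneth genes fell while 3, Mptx1, Copz2 and Tnfaip8, rose (14 and 4 adjusted over the list alone). For Paneth genes camera gave adjusted p = 0.00136, and adjusted p = 0.336 with an estimated correlation. Lysozyme (Lyz1, ENSMUSG00000069515, chromosome 10, 117287796 to 117292868) fell from 42863 ± 2935 to 7598 ± 2830.4 CPM (-2.53 ± 0.38, adjusted p = 0.00191). Angiogenin 4 (Ang4) fell from 3499.6 ± 74.8 to 385 ± 116 (-3.21 ± 0.36) and intelectin (Itln1) from 16542 ± 5799.9 to 3175 ± 226 (-2.33 ± 0.26). Goblet cell genes went both ways, with 6 higher and 5 lower of 23 (9 and 6 adjusted over the list alone; camera adjusted p = 0.444). Spink4, a secreted inhibitor of goblet granules, rose to 3721 ± 381 from 1272 ± 456 CPM and the kallikrein Klk1 to 663 ± 101 from 109 ± 16.9. The goblet and Paneth cell factor Spdef rose to 161 ± 32.2 from 69.0 ± 8.64, while Muc2, the main mucin, stood at 1216 ± 804 against 1277 ± 736 (adjusted p = 0.857).

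In hormone-producing enteroendocrine cells, 14 of 36 genes fell and 6 rose (15 and 7 adjusted over the list alone). For enteroendocrine genes camera gave adjusted p = 0.0249, and adjusted p = 0.550 with an estimated correlation. The granule protein Chgb fell from 462 ± 35.4 to 109 ± 13.5 CPM and Neurog3, which starts the lineage, from 11.3 ± 1.75 to 3.17 ± 1.38. Secretin (Sct, ENSMUSG00000038580, chromosome 7, 141278331 to 141279133) rose from 10.9 ± 5.79 to 161 ± 6.35 (3.98 ± 0.26, adjusted p = 6.78e-05) and the endocrine factor Pax6 from 4.02 ± 0.832 to 22.3 ± 6.32. The chemosensory tuft cell list was higher (median 0.96), with 2 of 20 genes, Nrep and Ptgs1, past the threshold (2 adjusted over the list alone). The tuft cell markers Dclk1, Trpm5 and Avil were higher in the run 440 pair and not in the run 385 means, while Alox5ap, Chat and Ltc4s were higher in both (in run 385 14.96 against 8.56, 3.94 against 1.16 and 3.86 against 2.55 CPM). Dclk1 stood at 36.8 against 5.34 CPM in run 440 and 43.7 against 62.3 in run 385, Trpm5 at 90.5 against 9.17 and 45.4 against 49.0, and Avil at 63.0 against 6.98 and 38.5 against 38.4. For tuft cell genes camera gave adjusted p = 0.00201, and adjusted p = 0.550 with an estimated correlation.

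Markers of cells beside the crypt moved too. Enterocyte genes were lower as a list (median -1.01), with 5 of 38 lower (5 adjusted over the list alone) and Dgat1 at -1.78 ± 0.33. For enterocyte genes camera gave adjusted p = 0.000599, and adjusted p = 0.550 with an estimated correlation. Immune genes were higher as a list (median 0.85), with 4 of 27 higher (2 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.550 with an estimated correlation). Laptm5, a lysosomal protein of blood cells, stood at 22.7 ± 5.69 against 8.78 ± 0.603 CPM. Both list calls were lost for 1 Eed KO against 1 WT crypt of run 440, where the enterocyte list pointed up. In that pair camera at the preset correlation called mesenchyme and mitochondrially encoded genes lower, with mt-Cytb at 5857 against 22442 CPM and mt-Nd4 at 2224 against 6860.4. For mesenchyme, muscle and endothelium (20 genes), enteric neurons and glia (5) and mitochondrially encoded transcripts (14), edgeR called no gene over all libraries, and 0 adjusted over the list alone. Their camera adjusted p-values were 0.668, 0.781 and 0.323.

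Fetal and regenerating epithelium re-expresses a known set of genes, and 14 of 18 measured rose (15 adjusted over the list alone; median 3.77). For fetal genes camera gave adjusted p = 3.92e-10, and adjusted p = 0.0567 with an estimated correlation. Among them were the interleukin-1 antagonist Il1rn (36.9 ± 4.13 against 0.882 ± 0.131 CPM), the annexin Anxa3 (60.4 ± 3.92 against 2.86 ± 2.01) and the EGF receptor ligand Areg (11.1 ± 5.75 against 0.280 ± 0.0204). Imprinted genes, expressed from 1 parental allele, rose in 11 of 24 cases (14 higher and 1 lower adjusted over the list alone). For imprinted genes camera gave adjusted p = 2.43e-06, and adjusted p = 0.0913 with an estimated correlation. Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), a fetal growth factor, went from 1.51 ± 0.298 to 79.2 ± 27.7 CPM (5.69 ± 0.27, adjusted p = 2.16e-05). The receptor signalling inhibitor Grb10 went from 4.67 ± 1.53 to 47.8 ± 10.7. Immediate early and heat shock genes, which respond to handling stress, rose in 6 and fell in 1 of 17 cases (7 and 1 adjusted over the list alone), with Nr4a1 at 3.54 ± 0.51. For immediate early genes camera gave adjusted p = 0.00491, and adjusted p = 0.202 with an estimated correlation. Interferon and antigen presentation genes split, with 9 of 34 higher and 10 lower, or 12 and 10 adjusted over the list alone. Ifi44 (2.08 ± 0.29) was among those higher, and the immunoproteasome genes Psmb8 (-1.80 ± 0.18) and Psmb9 (-1.74 ± 0.17) were lower. Their median (0.18) and mean (0.22) were above 0 and camera pointed down (adjusted p = 0.994). Of 9 aryl hydrocarbon receptor targets, which respond to the inducing compound, 2 rose (2 adjusted over the list alone; camera adjusted p = 0.294).

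Within the Polycomb complexes, 4 of 11 PRC2 genes fell (4 adjusted over the list alone), namely Eed, Ezh2 (-0.92 ± 0.14, adjusted p = 0.00212), Jarid2 (-0.73 ± 0.14) and Suz12 (-0.95 ± 0.29). For PRC2 genes camera gave adjusted p = 0.0453, and adjusted p = 0.202 with an estimated correlation. Ezh1 stood at 56.2 ± 8.26 against 57.2 ± 3.95 CPM (adjusted p = 0.922). PRC1 is the complex that reads the methyl mark, and 4 of its 19 genes rose (3 adjusted over the list alone; camera adjusted p = 0.359), with Cbx6 at 2.66 ± 0.39. The largest falls of single genes were in Cps1, a urea cycle enzyme also made by intestinal epithelium (199.9 ± 275 against 3758 ± 363 CPM, -5.43 ± 0.82), and in the pain receptor channel Trpa1 (-5.28 ± 0.52). They also took in Slc14a1, the organic anion carrier Slco2b1 (-4.75 ± 0.81), the meiotic Spo11 (-4.18 ± 0.79), Hemgn (3 KO counts in all, 47.8-fold lower by ratio, 16.0 to 235), Car4 and Apol10a. With same-numbered libraries as a block, the PRC2 list and 16 of 93 named genes lost their call, among them Jarid2, Suz12, Cbx8, Bmi1, Jag2, Dll1, Enpep, Krt20, Itgax, Tyrobp, Itgae, Gstm1, Gsta1, Car4 and Apol10a. Without the Ezh2 KO libraries and with no block, 7 lost theirs. Counts of lower genes moved by over 1.5 times without Eed KO 385_1 (804), WT 385_1 (950) or WT 385_2 (851).

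Does loss of Ezh2 do the same? In Ezh2 KO crypts edgeR called no Hox gene and no other developmental factor, and Cdkn2a, Olfm4 and Lgr5 did not pass the test. By edgeR, no gene was higher and 3 were lower of 14406 tested, 1179 had an unadjusted p under 0.05, and DESeq2 called 34 higher and 34 lower. Besides Ezh2, the 3 were the predicted pseudogenes Gm6472 and Gm7809, named after their values were seen. Ezh2 KO libraries were all in run 440, and values below are the mean ± SD of 3 Ezh2 KO crypts against the WT library of that run. Of 35 Hox genes and 71 other developmental factors, edgeR called 0, and 0 adjusted over the list alone (medians 0.14 and 0.09; camera adjusted p = 0.787 and 0.784). The homeobox factor Six4, outside these lists and named after its value was seen, was called lower by DESeq2 (1.14 against 4.80 CPM). Cdkn2a stood at 2 counts in all 3 libraries and Hoxb13 at 0. Olfm4 was 3519 ± 237 against 3828 CPM, Lgr5 129 ± 12.1 against 91.3, Mki67 357 ± 158 against 471 and Cdkn1a 65.6 ± 14.0 against 43.3.

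Paneth cell genes were lower in Ezh2 KO crypts as a list (median -0.57), with none of 25 called by edgeR over all genes and 2 lower adjusted over the list alone. In Ezh2 KO crypts camera gave them adjusted p = 1.72e-05, and adjusted p = 0.583 with an estimated correlation. Lyz1 was 17997 ± 6575 against 46105 CPM (log2 fold change -1.54 ± 0.44, adjusted p = 0.568), Itln1 10835 ± 2061 against 23201 and Habp2, a secreted protease, 120.0 ± 20.6 against 319. Immune genes were also lower as a list (median -0.60), with 0 of 27 called by edgeR over all genes and 5 lower adjusted over the list alone. Their camera adjusted p was 0.00203, and adjusted p = 0.951 with an estimated correlation. Immediate early and heat shock genes were higher (median 0.48), with 0 of 17 called by edgeR and 0 adjusted over the list alone (camera adjusted p = 0.00866, adjusted p = 0.583 with an estimated correlation). Bmi1, a PRC1 gene, was 76.9 ± 20.7 against 31.3 CPM (1.76 ± 0.41, adjusted p = 0.551), 1 of 19 adjusted over the list alone. In the interferon list 1 of 34 was higher adjusted over the list alone, and in the PRC2 list Ezh2 alone was called. Over all genes, DESeq2 called Lyz1, Habp2 and the mast cell genes Mcpt1 and Mcpt2 lower and Bmi1, Ifi44 and Ly6a higher. Camera adjusted p-values of the other lists ran from 0.106 to 0.874. Within run 440 alone, to which the CPM values above belong, camera at the preset correlation called 9 lists. Besides the 3 above, enterocyte, tuft and proliferation genes were higher and mesenchyme, goblet and mitochondrially encoded genes lower, while with no run term tuft genes were lower. For the stem cell, Wnt, Hox, PRC2, Notch, enteroendocrine and enterocyte lists the median, mean and camera differed in sign. Without WT 440_1, the sole WT library of that run, 254 genes were higher and 259 lower. Run and genotype then part only through the Eed KO crypts, and the WT crypts left have a male pattern, and which of these moved the counts was not tested.

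How far apart were the 2 knockouts? Developmental factors, Cdkn2a and Igf2 were higher in Eed KO crypts, and Olfm4, Lgr5 and proliferation transcripts lower. Igf2 stood at 79.2 ± 27.7 CPM in Eed KO and 1.72 ± 0.105 in Ezh2 KO crypts, against 1.58 in the WT library of run 440. Between them 1726 genes were higher in Eed KO and 1160 lower of 14406. Hox genes were higher in 30 of 35 cases (32 adjusted over the list alone), with camera adjusted p = 1.8e-24, and adjusted p = 0.081 with an estimated correlation. Other developmental factors were higher in 59 of 71 (60 higher and 3 lower adjusted over the list alone), with camera adjusted p = 2.97e-39, and adjusted p = 0.081 with an estimated correlation. Hoxb13 was at least 1002-fold, Hoxa10 at least 814-fold and Zic1 at least 730-fold higher in Eed KO. Cdkn2a had a ratio of 1415 (391 to 11691), and Igf2 a log2 fold change of 5.82 ± 0.28. Olfm4 was lower in Eed KO by -2.76 ± 0.28, Lgr5 by -1.81 ± 0.22 and Ascl2 by -1.70 ± 0.40 (adjusted p = 0.0194). In the stem cell list 9 of 28 were lower and 1 higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.0338, adjusted p = 0.667 with an estimated correlation). Proliferation genes were lower in 32 and higher in 1 of 42 cases (38 and 1 adjusted over the list alone; camera adjusted p = 1.09e-14, adjusted p = 0.106 with an estimated correlation).

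Of p53 targets 12 of 20 were higher in Eed KO (13 adjusted over the list alone; camera adjusted p = 1.09e-07, adjusted p = 0.081 with an estimated correlation). Fetal genes were higher in 13 of 18 cases (16 adjusted over the list alone; camera adjusted p = 3.2e-08, adjusted p = 0.081 with an estimated correlation). Imprinted genes were higher in 11 of 24 (14 adjusted over the list alone; camera adjusted p = 7.3e-06, adjusted p = 0.107 with an estimated correlation). Immune genes were higher in 10 of 27 cases (15 adjusted over the list alone; camera adjusted p = 4.25e-05, adjusted p = 0.434 with an estimated correlation). Tuft cell genes were higher in 6 of 20 (10 adjusted over the list alone; camera adjusted p = 0.00191, adjusted p = 0.667 with an estimated correlation). Enterocyte genes were lower in 4 of 38 (0 adjusted over the list alone; camera adjusted p = 0.000629, adjusted p = 0.667 with an estimated correlation). Lyz1 stood at 7598 ± 2830.4 against 17997 ± 6575 CPM (adjusted p = 0.150), and Sct was higher by 3.39 ± 0.28.

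In the remaining lists of Eed against Ezh2 KO crypts, no camera call was made. Higher and lower genes numbered 1 and 4 of 11 for PRC2 (2 and 4 adjusted over the list alone), 2 and 1 of 19 for PRC1 (2 and 0), and 2 and 2 of 7 for cell cycle inhibitors (2 and 2). In the same form, they numbered 3 and 3 of 20 for Wnt (5 and 3), 2 and 1 of 15 for Notch (2 and 1), 7 and 2 of 23 for goblet (7 and 2) and 1 and 2 of 25 for Paneth cells (1 and 2). They numbered 5 and 12 of 36 for enteroendocrine cells (6 and 13), 2 and 0 of 20 for mesenchyme (0 and 0), and 0 of 5 for enteric neurons and glia (0) and 0 of 14 for mitochondrially encoded genes (0). The last were 0 and 5 of 34 for interferon (0 and 5), 2 and 0 of 9 for aryl hydrocarbon receptor (2 and 0), and 3 and 1 of 17 for immediate early genes (3 and 1). The largest falls included Ang5 (at least 65.5-fold lower, but turned to 0.12 on the log2 scale without Eed KO 440_1), H2-Ea-ps, Rbpj-ps3 and Atp6v0c-ps2, pseudogenes or members of families with near-identical copies. WT crypts differed from each other at these genes. In the same order they stood at 5.28, 5.46, 1.70 and 8.86 CPM in WT 440_1, and at 0, 0.0897, 0 and 0.0883 in run 385 WT crypts. These falls therefore cannot be credited to the knockouts, and their cause was not tested. Without Eed KO 440_1, 1132 genes were higher, and without Ezh2 KO 440_2, 593 were lower.

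**Figure D2:**
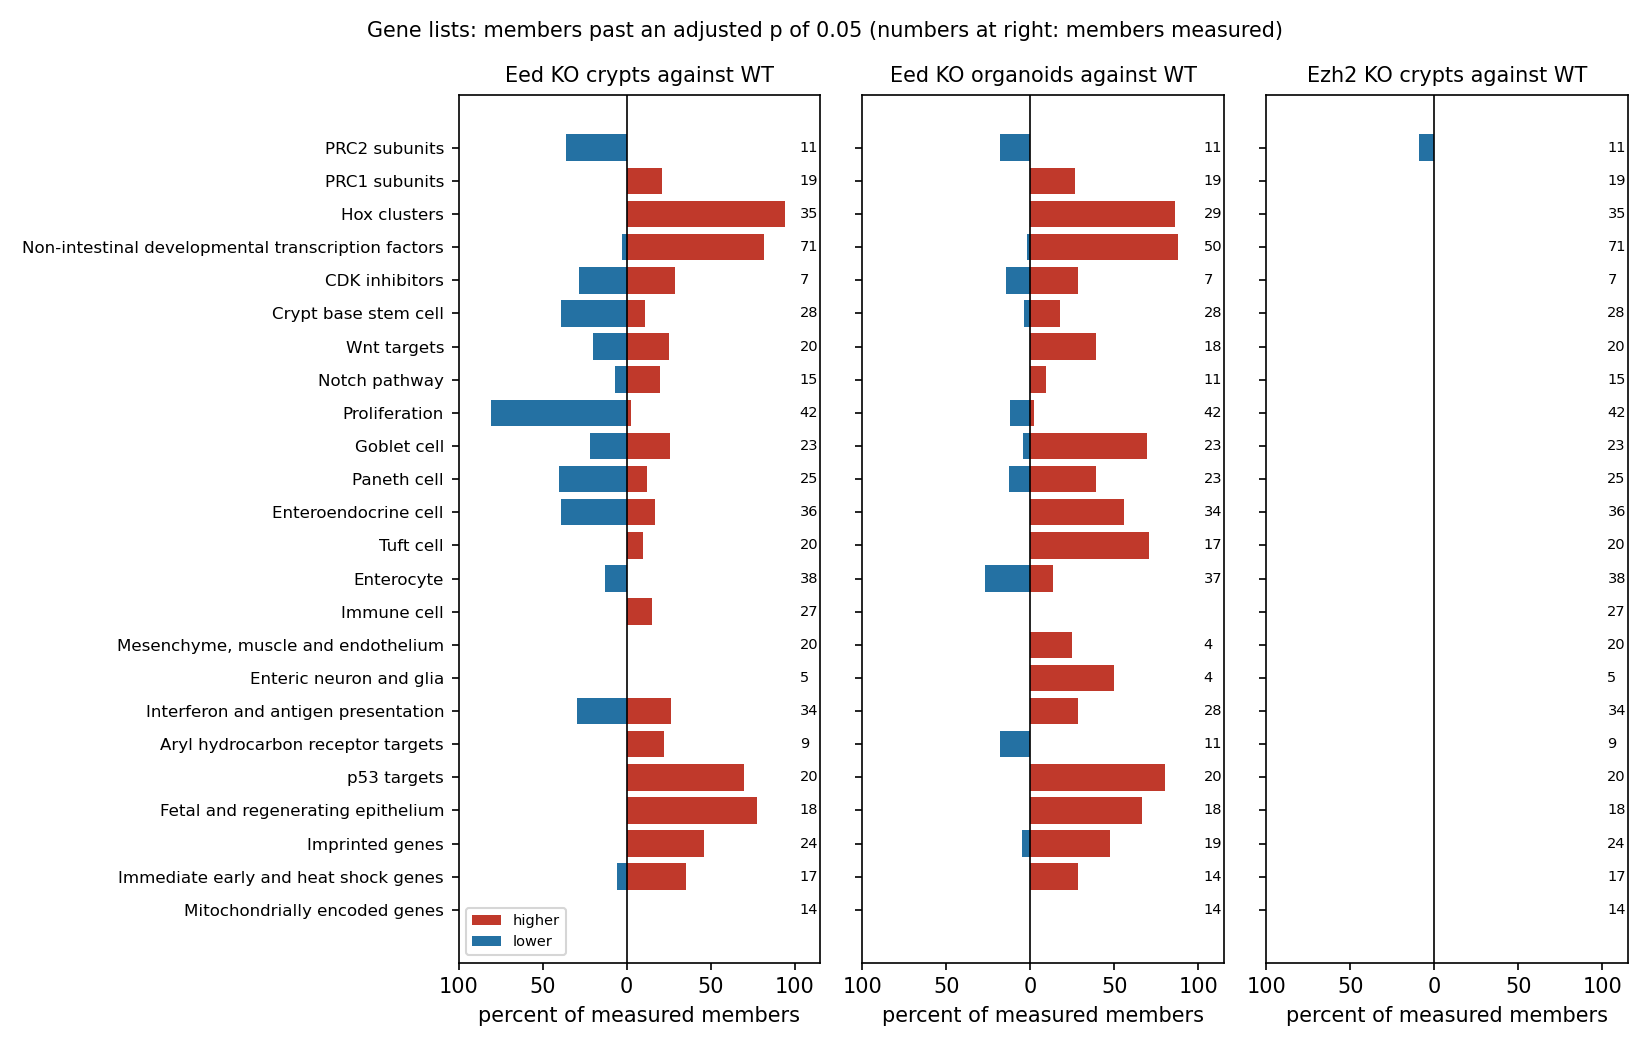
Percent of measured members of each gene list that were higher (right) or lower (left) at an adjusted p under 0.05, for Eed KO crypts, Eed KO organoids and Ezh2 KO crypts against WT, with the members measured at the right of each panel. Hox genes were higher in 33 of 35 cases in Eed KO crypts, 25 of 29 in organoids and 0 of 35 in Ezh2 KO crypts.

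What does loss of Eed change in organoids, where only epithelium grows and induction lasted 10 days? As in crypts, Hox genes, other developmental factors, Cdkn2a and Igf2 were higher. Goblet, enteroendocrine and tuft cell transcripts were higher too, while Mki67, Olfm4 and Lgr5 did not pass the test. Of 12958 genes, 1752 were higher and 600 lower. With the title number as a block, 2461 were higher and 1441 lower, and 269 were lower with all 13 libraries in 1 fit. Hox genes rose in 25 of 29 cases (25 adjusted over the list alone; median 6.87, or 4.98 at bounds). In organoids camera gave them adjusted p = 2.59e-20, and adjusted p = 0.308 with an estimated correlation. Other developmental factors rose in 44 of 50 cases, with 1 fall (45 and 2 adjusted over the list alone; median 6.88, or 4.30 at bounds), while the other genes of the 105 were not tested. Their camera adjusted p was 1.45e-25, and adjusted p = 0.138 with an estimated correlation. Hoxa10 reached 38.0 ± 4.63 CPM (n = 2) against no count (at least 311-fold higher) and Hoxa9 24.8 ± 4.50 (at least 203-fold). Ano3 reached 27.1 ± 3.36 (at least 222-fold) and the neural crest factor Pax3 12.6 ± 1.24 (at least 102.9-fold). Cdkn2a rose from 0.606 ± 0.112 to 51.0 ± 5.17 CPM (6.36 ± 0.23, adjusted p = 1.88e-05) and Cdkn1a from 146 ± 33.3 to 262 ± 18.5 (0.84 ± 0.17, adjusted p = 0.0152). Of 7 inhibitors 2 were higher and 1, Cdkn1b, lower (2 and 1 adjusted over the list alone; median -0.13, mean 0.91; camera up, adjusted p = 0.948).

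Stem cell genes were higher in 5 and lower in 1 of 28 organoid cases (6 and 2 adjusted over the list alone; camera adjusted p = 0.799). Lgr5 stood at 163 ± 52.8 against 205 ± 86.7 CPM (adjusted p = 0.638) and Olfm4 at 1328 ± 332 against 1867 ± 214 (adjusted p = 0.155). Tnfrsf19 (2.77 ± 0.34) and Cd44 (1.09 ± 0.12) rose and Slc14a1 fell (-5.96 ± 0.25). Wnt targets rose in 7 of 18 cases (9 adjusted over the list alone; camera adjusted p = 0.000253, adjusted p = 0.406 with an estimated correlation), with Lef1 at 5.38 ± 0.44. In the Notch list 1 of 11 genes, Atoh1, rose (1 adjusted over the list alone; camera adjusted p = 0.123). Proliferation genes were lower as a list by a small median of -0.16, with 5 of 42 lower and 1 higher (3 and 1 adjusted over the list alone). Their camera adjusted p was 0.00155, and adjusted p = 0.539 with an estimated correlation, and Mki67 stood at 610.1 ± 30.8 against 607 ± 59.7 CPM (adjusted p = 0.983).

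Goblet cell genes rose in 16 and fell in 1 of 23 organoid cases (19 and 1 adjusted over the list alone; camera adjusted p = 1.34e-07, adjusted p = 0.308 with an estimated correlation). Spink4 stood at 787 ± 70.7 against 242 ± 38.4 CPM, while Retnlb, another gene of the goblet list, fell to 2 counts (853-fold lower by ratio, 236 to 7052). Enteroendocrine genes rose in 19 of 34 cases (21 adjusted over the list alone; camera adjusted p = 4e-08, adjusted p = 0.405 with an estimated correlation). Somatostatin (Sst) stood at 65.8 ± 3.72 against 1.197 ± 0.293 CPM and Chga at 129.9 ± 23.2 against 36.0 ± 3.61. Tuft cell genes rose in 12 of 17 cases (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.52e-06, adjusted p = 0.405 with an estimated correlation). The tuft cell kinase Dclk1 stood at 8.87 ± 0.508 against 1.54 ± 1.42 CPM. Paneth genes rose in 9 and fell in 3 of 23 cases (11 and 3 adjusted over the list alone; camera adjusted p = 0.0139, adjusted p = 0.561 with an estimated correlation). Lyz1 stood at 1647 ± 525 against 1305 ± 180.3 CPM (adjusted p = 0.405) and the phospholipase Pla2g2a at 12.9 ± 0.944 against 688 ± 134. Enterocyte genes were split, 5 higher and 10 lower of 37 (5 and 12 adjusted over the list alone; camera down, adjusted p = 0.0272, adjusted p = 0.654 with an estimated correlation). The peptidase Dpp4 stood at 169 ± 4.46 against 3.69 ± 2.10 CPM and the phosphatase Alpi at 173 ± 12.2 against 422 ± 96.7.

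Among the other organoid lists, p53 targets rose in 16 of 20 cases (18 adjusted over the list alone; camera adjusted p = 9.22e-08, adjusted p = 0.414 with an estimated correlation). Fetal genes rose in 12 of 18 organoid cases (16 adjusted over the list alone; camera adjusted p = 1.07e-08, adjusted p = 0.406 with an estimated correlation). Imprinted genes rose in 9 of 19 and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.000116, adjusted p = 0.308 with an estimated correlation). Interferon genes rose in 8 of 28 (9 adjusted over the list alone; camera adjusted p = 9.05e-06, adjusted p = 0.534 with an estimated correlation). Immediate early genes rose in 4 of 14 (4 adjusted over the list alone; camera adjusted p = 0.0139, adjusted p = 0.534 with an estimated correlation). Igf2 stood at 80.1 ± 5.57 against 0.925 ± 0.554 CPM (6.46 ± 0.29) and the fetal marker Ly6a at 45.9 ± 13.5 against 2.69 ± 0.0772. Osteopontin (Spp1) stood at 46.6 ± 15.6 CPM against 3 counts (ratio 382, 130.4 to 1855) and the chemokine Cxcl10 at 9.04 ± 0.186 CPM against 2 counts (ratio 111, 30.3 to 921). The p53 target Zmat3 stood at 165 ± 9.56 against 54.9 ± 0.132. Aryl hydrocarbon receptor targets fell in 2 of 11 cases (4 adjusted over the list alone; camera adjusted p = 0.008, adjusted p = 0.384 with an estimated correlation), with the glutathione transferase Gstm1 at -1.34 ± 0.18.

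Of 11 PRC2 genes Eed and Suz12 (-0.41 ± 0.11) fell in organoids (2 adjusted over the list alone; camera adjusted p = 0.217), and Ezh2 stood at 100.4 ± 6.22 against 108 ± 0.754 CPM (adjusted p = 0.616). Of 19 PRC1 genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.123). In mesenchyme 1 of 4 rose (1 adjusted over the list alone; camera adjusted p = 0.858) and in enteric neurons and glia 2 of 4 (2 adjusted over the list alone; camera adjusted p = 0.101). Of 14 mitochondrially encoded genes none was called by edgeR (0 adjusted over the list alone; camera adjusted p = 0.227), while 3918 genes in all had an unadjusted p under 0.05. Sex-linked genes split along the male and female patterns (4 of 5 higher, 1 lower, 4 and 1 adjusted over the list alone). Their camera adjusted p was 0.00304, and adjusted p = 0.384 with an estimated correlation. The largest rises included the Y-linked Eif2s3y and Kdm5d beside Rdx, Gja1 and Npl. Largest falls after Xist and Retnlb were Atp6v0c-ps2, Ang5, Ear2, Hmga1b, Ear10 and Mrto4-ps2, among them pseudogenes and members of families with near-identical copies. Lower genes numbered 350 without Eed KO 385_1, and 1084 were higher and 255 lower without WT 385_1.

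Was the Eed effect the same in crypts and organoids? Of 12722 genes tested in both, 887 were higher and 248 lower in both, where independent lists give 204 and 67.3. Genes silent in WT pass the low-count filter mainly where a knockout raises them, which the expected 204 leaves out of account. The excess of shared higher genes may therefore be overstated. Of the 1187 genes called in both, 95.6% had the same sign. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.69 (covariance 1.38). The difference itself passed the test for 608 of 14761 genes, 167 with a higher and 441 with a lower fold in crypts, and 53 of these were called in both systems with opposite signs in the fit of all libraries. Leaving out 1 library moved the 608 to between 152 (without organoid WT 385_1) and 1284 (without crypt Eed KO 440_1). The fall of proliferation genes was larger in crypts (median difference -0.86; camera adjusted p = 1.51e-12, adjusted p = 0.125 with an estimated correlation). So was that of Olfm4 (-3.22 against -0.49, adjusted p of the difference 0.00213). Paneth (2.93e-07), goblet (0.000503) and enteroendocrine genes (4.81e-15) had lower folds in crypts by camera, with adjusted p = 0.125, 0.125 and 0.0880 with an estimated correlation. The folds of Cdkn2a (9.92 against 6.37, 0.0137) and Cdkn1a (2.87 against 0.84, 0.00808) were larger in crypts. For both genes the knockout levels given above were close in crypts and organoids. The gap in folds lay mainly in the WT levels, which were lower in crypts and near 0 counts for Cdkn2a. The systems also differed in sex pattern, strain label of WT and length of induction.

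**Figure D3:**
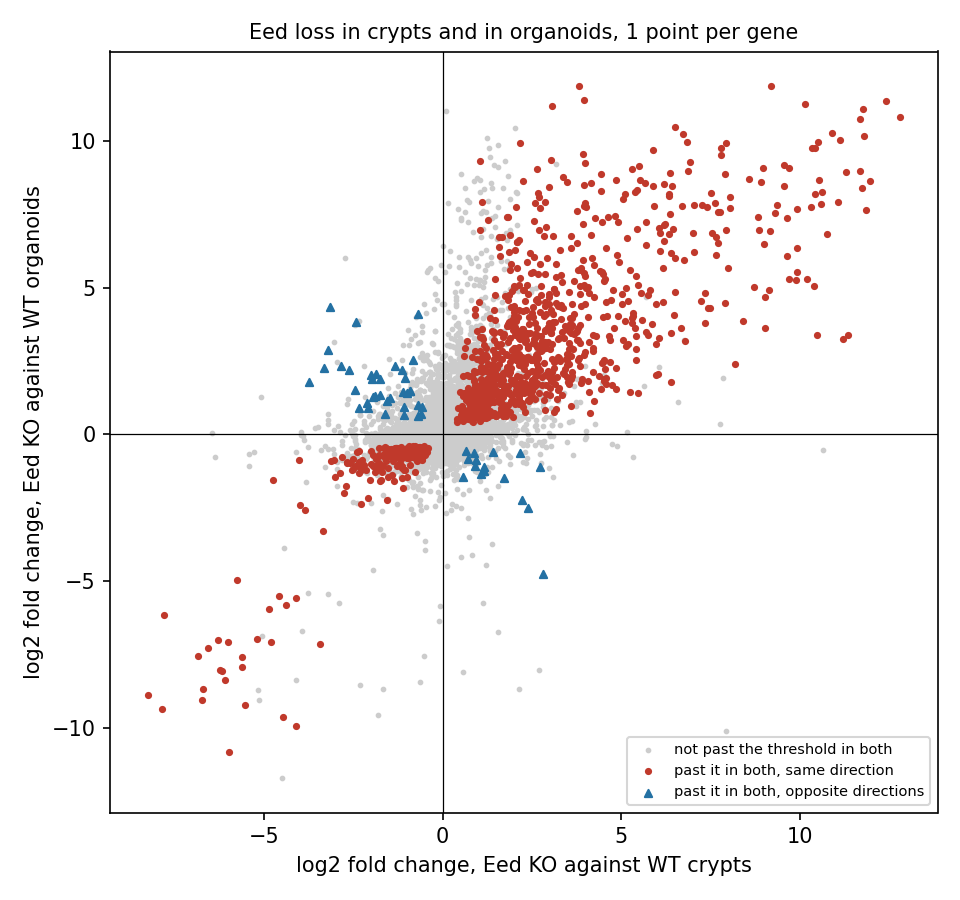
Log2 fold change of Eed KO against WT in organoids (y axis) and in crypts (x axis), with 1 point for each of 12722 genes. Red circles mark genes called in both systems with the same direction and blue triangles the 52 called in both with opposite directions, of 1187 in all.

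Eed and Ezh2 KO crypts were compared with the same 3 WT crypts, so their folds share the error of those libraries. By edgeR they could share no higher gene, since none was called in Ezh2 KO crypts. They shared 1 lower gene, Ezh2, where independent lists give 0.319. Simulated unchanged groups against these WT libraries shared at most 1 call in 20 simulations. With so few calls in either simulated group, little sharing was possible from the start. The simulations do not show what sharing or correlation arises when 1 knockout changes many genes. Across 14406 genes the log2 fold changes correlated at 0.14 (simulated mean 0.416, range 0.381 to 0.441) with a covariance of 0.136 (simulated mean 0.1003, highest 0.107). DESeq2 called 29 genes higher and 9 lower in both and 7 in opposite directions, and how many calls the shared WT crypts alone give by DESeq2 was not simulated.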

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

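Of the tests below, those of power, of the transcript left, of Ezh1, of sex in both systems, of enterocytes and of immune or stromal cells were chosen only after the results were seen, and the others before.

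Few genes were called in Ezh2 KO crypts: by edgeR 3, and by DESeq2 34 higher and 34 lower, against 3463 by edgeR in Eed KO crypts. Too little power with 1 WT library in run 440 was argued against for large changes only. Simulated 4-fold changes in genes with a mean above 20 counts were recovered at 72% for Ezh2 KO crypts. Only 24% of 2-fold changes were, so too little power stays open for smaller effects. A comparison of 1 Eed KO with 1 WT crypt of that run gave 1217 calls. Many Eed effects were large, so these calls cannot show power for smaller ones. The call of Ezh2 itself in Ezh2 KO crypts was lost with run 440 libraries only. A less complete loss of the targeted transcript was not seen, with 22.2% of WT Ezh2 left in Ezh2 KO crypts (18.9 of 85.4 CPM) against 19.003 of 54.1 CPM of Eed in Eed KO crypts. Transcript without the deleted exons counts as left in either knockout, and the labels do not name those exons. These levels therefore cannot rank how complete the 2 deletions were, and a less complete deletion of Ezh2 stays open. A rise of Ezh1 transcript was argued against by its log2 fold change of -0.47, and Ezh1 protein and methyltransferase activity, which the design does not measure, stay open as a biological explanation. Of the splits of the 6 libraries into 3 and 3, 1 of 10 gave as many calls for each crypt comparison, and 10 splits are too few for a share under 0.05: the real counts were 3463, 3 and 2886 and the highest of the others 1, 0 and 0, for Eed KO, Ezh2 KO and Eed against Ezh2 KO.

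The genotypes differed in sex pattern and, in organoids, in strain label, which could account for part of the Eed calls. Sex in run 385, where WT crypts had a male and Eed KO crypts a female pattern, stays open for part of them. Of the 3875 genes called in run 385 alone, 83.5% had the same direction in run 440, where all crypts had a female pattern. This share lies between bounds that were set in advance for the calls of the crypt fit. Of 3452 such calls, 99.7% had the same direction in run 440, but that fit holds the run 440 libraries, so their share cannot decide. As the cause of the calls made in both crypts and organoids, sex was argued against, since the sex pattern was opposite in the 2 systems and 95.6% of 1187 shared calls had the same direction. Strain as the cause of the organoid calls stays open. Of 2266 organoid calls, 86.1% had the same direction in crypts, which have 1 strain label. But WT crypts of the 2 runs differed at genes that part the organoid genotypes, so that label may not mean 1 background. Vcp-rs stood at 59.9 CPM in WT crypts of run 385 and 0.0607 in that of run 440. Its log2 fold change in Eed KO organoids was 9.75. For Atp6v0c-ps2 these were 0.0883 and 8.86 CPM and -10.96 (fit of all libraries). Both genes were chosen after their values were seen. Loss of Eed, the difference the design names, stays open beside strain, and beside sex too for genes called in only 1 system.

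Proliferation and stem cell transcripts were lower in Eed KO crypts, and the fall of proliferation genes was larger there than in organoids. A larger share of villus enterocytes stays open, since the median log2 fold change of -1.01 for the enterocyte list (mean difference -1.08, SE 0.564) lay under 2 SE from 0 and within run 440 that list pointed up without a call. A larger share of immune or stromal cells stays open too. It would lower goblet transcripts as much as proliferation transcripts if loss of Eed itself left goblet genes unchanged. The goblet list lay 1.12 (SE 0.176) above the proliferation list on the log2 scale. But goblet genes rose in 16 of 23 cases in Eed KO organoids, so this contrast cannot decide the question. The Paneth and enteroendocrine lists fell as well. A first test on the lower of the immune and mesenchyme medians (0.199, SE 0.814) had also left it open. Whether the difference from organoids was within the noise also stays undecided, with adjusted p = 1.51e-12 at the preset correlation and 0.125 with an estimated one. An effect of Eed loss that may need 6 weeks in the animal rather than 10 days in culture, or cells around the epithelium, was not tested, because system, time, sex and strain changed together.

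The other results are differences in the Eed effect between crypts and organoids, each with its adjusted p by edgeR or camera. In all 608 of 14761 genes differed (152 without organoid WT 385_1 to 1284 without crypt Eed KO 440_1), and of the named genes 54 of 188. Of genes that mark the sex patterns, Ddx3y and Eif2s3y had 0.000131, Kdm5d 0.00276 and Xist 0.0255. Folds were higher in crypts for Gsta3 (4.75 against -0.33, 0.000131), Ephx1 (3.30 against 0.32, 0.000427), Gsta4 (3.98 against -0.15, 0.000427), Aqp8 (10.62 against -0.54, 0.000593), Areg (5.28 against 1.44, 0.00176) and Gdf15 (4.74 against 1.69, 0.00257). They were also higher in crypts for Gstm1 (0.00504), Cdkn1a (0.00808), Plk2 (0.00933), Cdkn2a (0.0137), Zmat3 (0.0217), Psrc1 (0.0268), Anxa3 (0.04301) and Atp6v0e2 (0.000427). Among endocrine genes the fold was lower in crypts for Chgb (-2.10 against 0.91, 0.000427), Sst (-0.04 against 5.78, 0.000427), Pcsk1 (0.00116), Chga (0.00213), Gip (-1.86 against 2.04, 0.00326) and Pax6 (0.0403). Among secretory cell genes it was lower for Itln1 (-2.33 against 0.89, 0.00169), Capn9 (0.00169), Habp2 (0.0023), Ang4 (0.00409), Clps (0.0129), Lyz1 (-2.54 against 0.34, 0.0152), Defa30 (0.0211) and Zg16 (0.0253). Among stem cell and proliferation genes it was lower for Olfm4 (0.00213), Tnfrsf19 (0.0159), Apcdd1 (0.00213), Birc5 (0.00763), Tpx2 (0.00997), Ccna2 (0.0126) and Ccnb1 (0.01603). Among interferon genes it was lower for Gbp7 (0.0125), Psmb8 (0.0145), Nlrc5 (0.0261), Cxcl10 (0.0429) and Ifi44 (0.0483). The rest with a lower fold in crypts were Dpp4 (-0.43 against 5.53, 0.000427), Itga1 (0.000427), Nrn1 (0.00105), Trpa1 (0.00526), Rdx (0.0159), Npl (0.0219), Hemgn (0.0225), Cps1 (0.0255), Ezh2 (0.041) and Klf6 (0.0494).

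By camera 13 of 25 lists differed, and 0 with an estimated correlation, where the lowest adjusted p was 0.0801. Folds were lower in crypts for stem cell (0.00308), Wnt (0.0323), proliferation (1.51e-12), goblet (0.000503), Paneth (2.93e-07), enteroendocrine (4.81e-15), interferon (1.51e-12) and sex-linked genes (0.0323). They were higher in crypts for developmental factors (3.46e-21), aryl hydrocarbon receptor targets (0.0031) and p53 targets (8.99e-06). Hox genes also had a call upwards (2.1e-05), while their median difference was -0.22. The call of immune genes upwards (0.00126) is no evidence of a difference, since only 2 of 28 were measured in organoids and none passed singly. Over the 12722 genes tested in both systems, a check chosen after the results were seen, 11 of 23 lists differed. These were the lists above other than the immune and sex-linked ones, which were not tested, with developmental factors at 2.72e-16 over 49 genes (0.0317 with an estimated correlation, the only list to pass so) and Hox genes at 2.94e-05 with a median difference of -0.02.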

How the results depend on the processing

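The alternatives of 1 Eed KO against 1 WT crypt in run 440, of lists within run 440, of Eed KO crypts without the Ezh2 KO libraries, of lists over genes tested in both systems, of genes without the X and Y chromosomes and of the interaction without each library were chosen after seeing the data. Counts of genes higher in Eed KO crypts, in Eed against Ezh2 KO crypts and in Eed KO organoids stayed within 1.5 times of their value under all alternatives other than leaving out 1 library, except the replicate block and 1 against 1 in run 440 for Eed KO crypts. With DESeq2 size factors in edgeR, all counts stayed within that range, at 1902 higher and 1581 lower for Eed KO crypts, of which 1900 and 1520 were among the reported ones. No paired analysis was possible for Ezh2 KO against WT and for Eed against Ezh2 KO crypts, because those libraries share only 1 number. In organoids, same-numbered deviations correlated at 0.479, where 2 pairs share only a number, and the block gave 2461 higher and 1441 lower. In crypts the block, fitted without the Ezh2 KO libraries (13802 genes), left 1046 higher and 543 lower, while leaving out those libraries with no block gave 1465 and 999, so part of the move is not the block's. Depth limits what could be seen near 0 counts, and where a group was left with 1 library, that library was assumed to vary like the others.

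Counts that moved are given with the reported values first, and the cause was not tested unless a reason is named. For Ezh2 KO crypts, 0 higher and 3 lower became 3 and 5 with no low-count filter, 34 and 34 by DESeq2, 1 and 1 with run 440 libraries only, 5 higher with all 13 libraries in 1 fit, 2 higher with no run term and 1 lower without genes of the X and Y chromosomes. For Eed KO crypts, 1932 higher and 1531 lower became 741 and 476 for 1 against 1 in run 440, where fewer libraries were compared, and 730 lower with no run term. For Eed against Ezh2 KO crypts, 1160 lower became 1878 by DESeq2. In organoids, 600 lower became 269 with all 13 libraries in 1 fit. The 608 genes that differ between crypts and organoids became 1360 with run 385 libraries only and 1203 by DESeq2. Shared calls of Eed and Ezh2 KO crypts went from 1 to 38 by DESeq2 and to 0 at a threshold of 0.01, and those of crypts and organoids from 1135 to 523 at a threshold of 0.01. Lists past the threshold by camera, 14 for Eed KO crypts, 3 for Ezh2 KO crypts, 10 for Eed against Ezh2 KO crypts and 16 for organoids, became 0, 0, 0 and 0 with an estimated correlation. By fry they were 12, 0, 9 and 14, and for Ezh2 KO crypts 9 with no run term and 9 with run 440 libraries only.

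Leaving out 1 library at a time gave 1289 to 2433 higher and 804 to 1939 lower for Eed KO crypts, with fewer lower without Eed KO 385_1 (804), WT 385_1 (950) or WT 385_2 (851). For Ezh2 KO crypts it gave 0 to 254 higher and 1 to 259 lower. WT 440_1 decides the upper ends (254 and 259 without it), and 1 was lower without Ezh2 KO 440_3 or WT 385_2. For Eed against Ezh2 KO crypts it gave 1132 to 1727 higher and 593 to 1292 lower, with 1132 higher without Eed KO 440_1 and 593 lower without Ezh2 KO 440_2. For organoids it gave 1084 to 1583 higher and 255 to 685 lower, with 1084 and 255 without WT 385_1 and 350 lower without Eed KO 385_1. The genes that differ between crypts and organoids numbered 152 to 1284. They were 350 without crypt Eed KO 385_1, 1284 without crypt Eed KO 440_1, 1243 without crypt WT 440_1 and 258 without crypt WT 385_2. Without organoid Eed KO 385_1 they were 286, without Eed KO 385_2 342, without WT 385_1 152 and without WT 385_2 180.

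Of the genes named, some turned their sign. By DESeq2, 1 did in Eed against Ezh2 KO crypts: Hmga1b went from -5.85 to 0.70, and it ran from -7.29 to 4.47 without 1 library. Eed KO 440_1 decides this gene and the next 3, since without it the sign turned. So it was in Eed against Ezh2 KO crypts: Ang5 went from -7.75 to 0.12 (lowest -8.28 without 1 library). The same held in Eed against Ezh2 KO crypts: Ccnb1ip1 went from -7.11 to 0.71 (lowest -7.64). The last was in Eed against Ezh2 KO crypts: Trpm5 went from 2.21 to -0.59 (highest 2.45). For 1 against 1 in run 440, where both libraries had a female pattern, Xist (-2.46) and Tsix (-8.20) turned in Eed KO crypts. Without WT 440_1, the WT crypts left had a male pattern, and 2 genes turned in Ezh2 KO crypts: Tsix went to 8.16 (lowest -2.23). The other was in Ezh2 KO crypts: Xist went to 11.18 (lowest -0.47). Of 93 named genes called in Eed KO crypts, 16 lost their call with the replicate block, 7 without the Ezh2 KO libraries, 17 with no run term, 35 for 1 against 1 in run 440 and 6 with no low-count filter. Of 129 called in Eed against Ezh2 KO crypts, 48 lost theirs without Eed KO 440_1, 13 with no run term and 10 with no low-count filter, and of 89 in organoids 12 did with all 13 libraries in 1 fit. The call of Ezh2 in Ezh2 KO crypts was lost with run 440 libraries only and without Ezh2 KO 440_2, Ezh2 KO 440_3 or WT 385_2. Of the named genes not called there, 9 gained a call by DESeq2.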

Other observations

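Of the tests in this part, the overlap of DESeq2 calls with organoid calls was chosen only after the values were seen, and the tests of the organoid set and of passenger genes before.

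Of the 1932 genes higher in Eed KO crypts, 721 (37.3%) had under 1 CPM in WT, and of the 1752 higher in Eed KO organoids 830 (47.4%). Over all genes tested, 1570 of 14406 (10.9%) were this low in WT crypts and 1239 of 12958 (9.56%) in WT organoids. Such genes pass the low-count filter mainly where a knockout raises them, so the filter in part sets these shares. Genes this low in WT can hardly be called lower, so no share of lower genes is set beside these. Among the genes with the smallest p for a difference between the systems, the glutathione transferases Gsta3 (4.75 against -0.33) and Gsta4 (3.98 against -0.15) and the water channel Aqp8 (10.62 against -0.54) had higher folds in Eed KO crypts than in organoids. For Gsta1 (2.82 against -0.26) the difference did not pass (adjusted p = 0.146).

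DESeq2, which called more genes than edgeR in Ezh2 KO crypts, put 34 higher there, and the examples below were chosen after their values were seen. Lin28b, an RNA-binding protein of embryonic cells, stood at 3.71 CPM in Ezh2 KO crypts and at 0 in the WT library of run 440. Cecr2, a chromatin remodelling factor, stood at 6.14 against 0.971 CPM, Wfdc2, a secreted protease inhibitor, at 3.39 against 0.911, and Mid1, a ubiquitin ligase of microtubules, at 62.4 against 3.89. In Eed KO organoids, Lin28b had a log2 fold change of 5.30, Cecr2 of 5.80 and Wfdc2 of 4.31. Among the 34 lower were Ezh2, Lyz1, the gut hormone gene Gcg (20.9 against 67.7) and the mast cell protease Mcpt1 (1.35 against 7.35), and pseudogenes such as Rps3a3. Rps3a3 stood at 168 CPM in run 385 WT crypts and at 0.425 in the WT crypt of run 440, against 0.311 in Ezh2 KO crypts, so its fold rests on WT libraries that differ from each other.

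A candidate explanation for these calls was a weaker form of the change that follows loss of Eed. Of the 34 genes, 31 were tested in organoids and 19 were higher there, where independence gives 4.11 (Fisher's exact test, 2-sided p = 5.47e-10). But genes silent in WT, as Lin28b was in WT crypts, pass the low-count filter mainly where a knockout raises them. Of 1239 tested genes under 1 CPM in WT organoids, 830 were higher in Eed KO organoids. The expectation over all genes is too low for such genes, so this overlap and its p-value cannot decide the question. The organoid libraries share no control with the crypts. Over the 1685 genes higher in Eed KO organoids, however, the median log2 fold change in Ezh2 KO crypts was -0.0187 relative to the 12721 other genes, with camera p = 0.832, or 0.930 with an estimated correlation. A common shift of that whole set was therefore argued against. For the 765 of them under 1 CPM in WT organoids the median was 0.0462, against -0.0981 for 361 other genes under that bound, a difference of 0.144. The 2 sets share this bound only and were not matched in level below it. Of these 765 genes, 53.1% were above 0, against 45.2% of the 361. That difference was not tested, so a small shift of silent genes stays open, as does an effect on a few genes.

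Genes close to the targeted allele could carry variants of the strain in which it was made. Within 10 megabases of Eed, 15.1% of 106 genes were called in Eed KO crypts, against 24.1% of 14300 elsewhere, a ratio of 0.626 (Fisher's exact test, 2-sided p = 0.0300). In organoids the shares were 20.2% and 18.1%, and near Ezh2 in Ezh2 KO crypts, at an unadjusted p under 0.05, 6.15% and 8.20%. An excess of called genes close to the targeted alleles was argued against by these shares. They cannot decide on strain differences over the whole genome, as the organoid labels allow, since genes elsewhere could carry those too.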
